A study of Oryza sativa with 26 samples.

How the data were processed

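Rice anthers (Oryza sativa; the labels give no cultivar) were profiled on 26 Affymetrix Rice Genome Arrays, 3 or 4 for each of 8 stages of development. Per the labels, the plants grew in paddy fields at Mishima under normal conditions, the anthers were frozen in liquid nitrogen and stored frozen, RNA was taken with an RNeasy plant mini kit, and biotinylated cRNA was made from 500 ng of total RNA. The submitters' processing notes name GCOS 1.3 but do not say which step it did. The deposited values are intensity on a linear scale, and no detection calls or background settings are given. The values show that the authors divided each array by its own 75th percentile: over all 57381 probe sets that percentile is 1 on each of the 26 arrays. An array value has no count behind it, so the number of arrays limits the precision.

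Values were analysed as log2(intensity + 1). The rule for the pseudocount, the 20th percentile of all pooled values rounded to a whole number of at least 1, was written for another intensity scale; the percentile was 0.149, so 1 was used and changes at low intensities are compressed. The array medians were not aligned further. Of 57194 probe sets, after 187 control probe sets were left out, those with a stage mean above the 40th percentile of all log2 values in at least 1 stage were tested, which kept 47799 (83.6%). All 26 arrays were used. The probe set was the unit; 22436 name 1 gene, 95 name several genes and were given no name, and 34663 name none. Symbols came from the gene table deposited with the array and from a RefSeq gene table of assembly ASM3414082v1, which was used for names alone; 2457 of the 17905 single genes had a symbol. Wherever 1 value per gene was needed, the probe set with the highest mean over the 26 arrays was taken.

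The stages, comparisons, thresholds, hand-written gene lists and alternative settings were chosen before the data were examined. A fit with stage means was made over all 26 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance. The tests were an F test over the 8 stages, a test of each of the 7 transitions between consecutive stages, and tests of each stage against each of the other 7. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its test and a log2 difference of at least 1; for the F test the stage means had to span 1 log2 unit, and for a stage-enriched probe set all 7 differences had to pass. All tests were two-sided. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

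Gene lists were tested at each transition with limma's camera at a preset correlation of 0.01, adjusted over the 168 tests of 24 lists, and again with an estimated correlation; limma's fry was an alternative. Lists needed 3 measured members. Of the genes listed, 4 of 17 were measured for the tapetal lipid list, 11 of 26 for meiosis and 6 of 20 for starch synthesis. The hand-written lists covered anther wall and tapetum regulators, the tapetal lipid and sporopollenin pathway, tapetal proteases, meiosis, DNA replication and the mitotic cell cycle, starch synthesis, anther sugar supply, late pollen, gibberellin, stamen identity MADS-box genes and other floral organs. Planned lists by product name could not be built, since the tables hold no product names. In their place lists by symbol were written after the tables were opened and before any gene's values were examined: core histones, cytosolic ribosomal proteins, photosynthesis, lipid transfer proteins, alpha-expansins, beta-expansins, heat shock proteins and factors, proteasome subunits, the actin cytoskeleton and calcium-dependent protein kinases. Those of kinesins, DNA replication factors, cellulose synthases, potassium transporters, auxin response and jasmonate response genes were new at that point, and a pectin list could not be made. Lists of small heat shock, dehydration and jasmonate synthesis genes were written after values were seen.

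The genes named were set by a rule: per transition the 6 largest rises and the 6 largest falls among called probe sets of 1 gene with a symbol and non-overlapping replicates, and up to 3 called members of each list called by camera; per stage the 4 stage-enriched genes with the largest margin; and per hand-written list the 4 members with the highest F statistic. Genes outside the rule are said to be chosen after their values were seen.

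The fit was tested on simulated data with the same design: of 100 probe sets with a log2 step of 1.5, 96 to 99 were recovered at each transition, with at most 5 false calls. The simulated noise was independent between probe sets and had the same SD in every stage. These rates may therefore not hold for the real arrays, whose spread differs between stages. Each result was recomputed with a pseudocount of 4, without the filter, with a filter at the 60th percentile, with quantile normalization, with median-centred arrays, without the trend, with array weights, without probe sets that can bind related transcripts, with 1 probe set per gene, with the replicate number as a block, with the arrays of the 2 stages alone, and without each array in turn. A gene whose probe set was removed by a setting was not compared under it. A planned pseudocount of 1 was the value already in use. Added after the data were seen were a pseudocount of 0.149, scaling to the hybridization spike-in controls, and leaving out P3 replicate 1 and P2 replicate 1 together. The same tests were run on other splits of the arrays, up to 100 for each result.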

Results

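Transcript levels were measured in rice anthers (Oryza sativa) with the Affymetrix Rice Genome Array, on which each transcript is read by 1 or more probe sets. The 26 arrays followed anther development through 8 stages, from the first archesporial cells to mature pollen. An1 (3 arrays) is the stage at which hypodermal archesporial cells form, and Mei1 (3 arrays) is premeiotic S or G2 phase. Meiosis is covered by M1 (leptotene, 4 arrays), M2 (zygotene to pachytene, 3 arrays) and M3 (diplotene to tetrad, 4 arrays). Pollen development is covered by P1 (uninucleate gametophyte), P2 (bicellular) and P3 (tricellular, mature pollen), with 3 arrays each. The titles call the arrays of a stage biological replicates. Values are deposited intensities divided by the 75th percentile of their array, which is 1 on every array. The array medians ran from 0.242 to 0.428, and the number of arrays limits the precision. Means are given with their SD over the arrays of a stage, in the order of the stages compared, and log2 changes are the later minus the earlier stage on log2(intensity + 1). Genes named as risen or fallen had replicate values that did not overlap between the 2 stages compared, except where an overlap is stated.

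The array profiles were ordered by stage, and pollen maturation separated them most. Across probe sets, which are not independent replicates, the mean profiles of An1 and Mei1 correlated at r = 0.995 (Pearson), those of P1 and P2 at 0.830, and those of P2 and P3 at 0.827. The first principal component held 49.1% of the variance and ran from An1 to P3. The second held 17.8% and separated M3 and P1 from the earliest and the latest stages. Replicates within a stage correlated at 0.925 or more in An1 to P2, but at 0.836 at the lowest in P3. P3 replicate 1 stood apart: its mean correlation with the other P3 arrays was 0.842, and its correlation with P2 replicate 3 was 0.890. The Mei1 arrays were about as close to an An1 array (0.990, 0.990 and 0.992) as to the nearest array of their own stage (0.990 each). M2 replicate 2 and P3 replicate 1 carried the highest levels of small heat shock protein transcripts in the series. The list means were 3.58 and 3.60 on the log2 scale against at most 2.10 on the other 24 arrays.

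**Figure D1:**
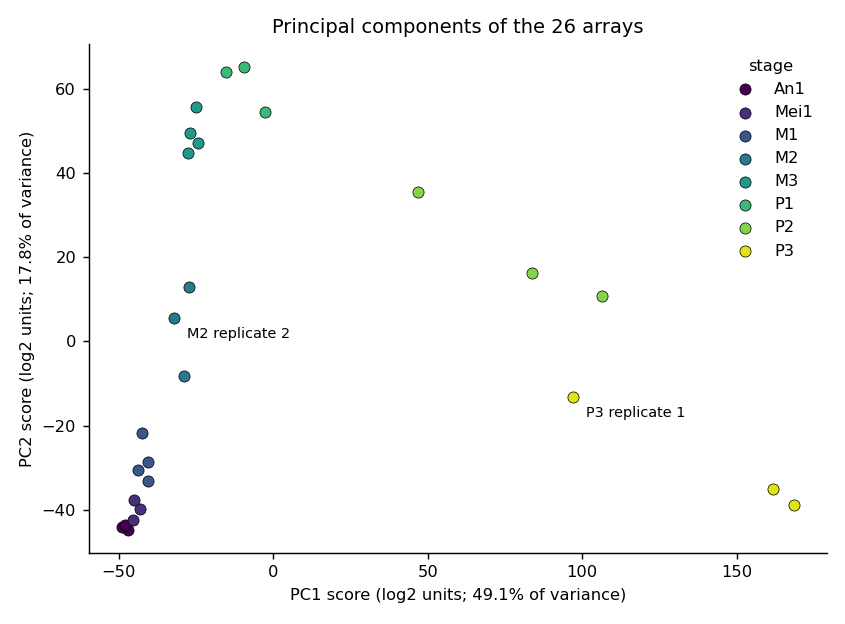
Scores of the 26 arrays on the first principal component (x axis, log2 units, 49.1% of the variance) and the second (y axis, log2 units, 17.8%), each point 1 array coloured by stage. An1 and Mei1 lie together at the left, and P3 replicate 1 lies beside the P2 arrays while the other P3 arrays lie at the far right.

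Which transcripts changed at any point of development was asked first. MEL1, the germ-cell Argonaute, was highest in An1 (45.8 ± 2.39, n = 3) and lowest in P3 (0.463 ± 0.0799, n = 3). KAO, a gibberellin synthesis enzyme, was highest in P2 (52.8 ± 13.7, n = 3) and lowest in M1 (0.276 ± 0.0136, n = 4). The tapetal lipid transfer protein gene C6 was highest in P1 (146 ± 17.3, n = 3), against 0.147 ± 0.0391 in An1. All 12 measured genes of DNA replication and the mitotic cell cycle changed, each of them highest in An1. So did all 8 anther wall and tapetum regulators and 23 of 25 cytosolic ribosomal protein genes. Fewer members of the meiosis list passed, 5 of 11 measured being past both thresholds, among them PAIR2 (9.04 ± 0.514 in Mei1 and 0.547 ± 0.00770 in P3) and the kinesin gene PSS1 (3.06 ± 0.202 in Mei1 and 0.429 ± 0.115 in P3). By the limma F test, 11560 of the 47799 probe sets tested (24.2%) had an adjusted p under 0.05 and stage means at least 1 log2 unit apart, and they represented 7901 genes. At the adjusted p alone the count was 40819. Of the 11560, 3282 were highest in P3, 2230 in An1 and 1959 in P2, and 3551 were lowest in P3. The number depends on the pseudocount: 5070 probe sets passed with a pseudocount of 4 in place of 1, and 20856 with 0.149.

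**Figure D2:**
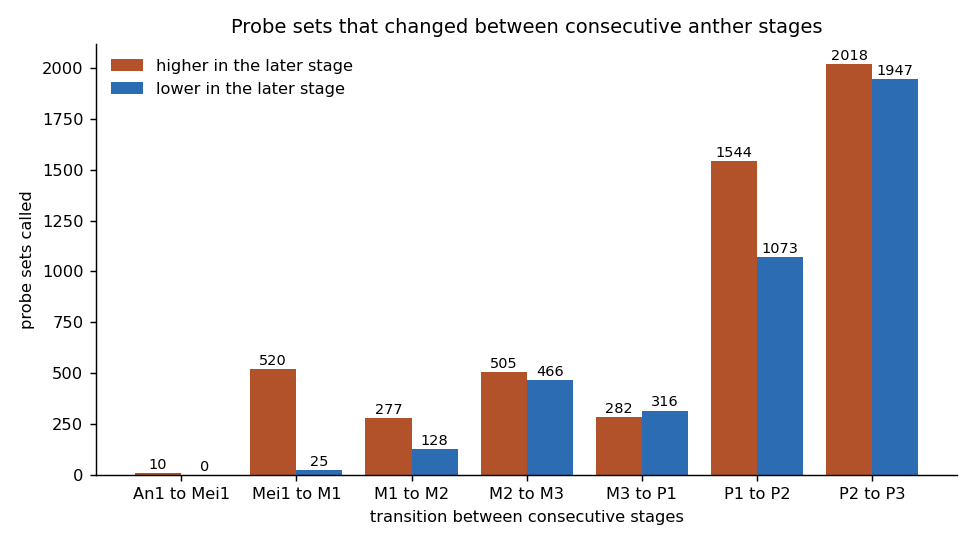
Number of probe sets (y axis) called higher (brown) or lower (blue) in the later stage at each of the 7 transitions between consecutive stages (x axis). The smallest count is 10, from An1 to Mei1, and the largest are 2617 from P1 to P2 and 3965 from P2 to P3.

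Between An1 and Mei1, archesporial anthers were compared with premeiotic ones, and few transcripts passed both thresholds. By limma, 10 of the 47799 probe sets tested were called, all higher in Mei1, and 0 were lower. An unadjusted p under 0.05 was reached by 1183, a smaller share than the 0.05 that chance alone would give. The spread in the fit is shared by all 8 stages. Replicates correlated at 0.975 or more in An1 and Mei1, but at 0.836 at the lowest in P3. The test may therefore miss changes between An1 and Mei1. Of the 10, 4 have a gene, none with a symbol, and they are named here after their values were seen. LOC4336063 went from 4.0 ± 2.17 to 17.9 ± 4.06 (log2 change 2.0, adjusted p = 0.0074), and LOC4340504 from 2.11 ± 1.13 to 9.20 ± 2.82 (log2 change 1.74), with 3 arrays in each stage. LOC4344442 went from 0.883 ± 0.490 to 3.44 ± 0.751 (log2 change 1.25) and LOC4326594 from 0.917 ± 0.313 to 2.93 ± 0.751 (log2 change 1.03). Among the gene lists, the 8 anther wall and tapetum regulators shifted higher (median 0.33, adjusted p = 0.00248, and adjusted p = 0.215 with an estimated correlation). Over all probe sets 0 of the 8 were called by limma and 2 had an unadjusted p under 0.05, while 1 was higher when adjusted over the list alone. That 1 was EAT1 (LOC4336865), a bHLH regulator of the tapetum, with 1.40 ± 0.807 in An1 and 6.43 ± 2.16 in Mei1 (adjusted p = 0.15 over all probe sets), chosen after its values were seen. The 12 DNA replication and mitotic cell cycle genes shifted lower (median -0.31, adjusted p = 1.14e-06, and adjusted p = 0.334 with an estimated correlation). So did the 26 DNA replication factors (median -0.15, adjusted p = 0.00978, and adjusted p = 0.749 with an estimated correlation), the 34 kinesins (median -0.11, adjusted p = 1.61e-07, and adjusted p = 0.231 with an estimated correlation) and the 6 core histones (median -0.23, adjusted p = 0.0043, and adjusted p = 0.365 with an estimated correlation). The 16 proteasome subunits (median -0.23, adjusted p = 7.47e-09, and adjusted p = 0.334 with an estimated correlation) and the 6 genes of other floral organs (median -0.12, adjusted p = 0.0281, and adjusted p = 0.346 with an estimated correlation) were also lower. The 11 meiosis genes shifted higher (median 0.04, adjusted p = 0.00346, and adjusted p = 0.259 with an estimated correlation). By limma, 0 members of these 7 lists were called, and 3, 0, 11, 1, 3, 1 and 3 had an unadjusted p under 0.05, in the order given. The count of 10 was 0 without An1 replicate 1 or Mei1 replicate 3, 2 without An1 replicate 2, 3 without Mei1 replicate 2, 3 under spike-in scaling, 36 with array weights and 35 with only these stages' arrays, and calls were lost for LOC4344442 (adjusted p = 0.0447) without any 1 of 16 arrays (0.0523 to 0.529), for LOC4340504 and LOC4326594 without An1 replicate 1 (0.264 and 0.23), An1 replicate 2 (0.103 each), Mei1 replicate 2 (0.0962 and 0.0668) or Mei1 replicate 3 (0.143 and 0.148), for LOC4336063 without An1 replicate 1 (0.11) or Mei1 replicate 3 (0.0663), for the first 3 under spike-in scaling (0.0526, 0.0725 and 0.309), for LOC4344442 (0.208) and LOC4326594 (0.0768) with a pseudocount of 4, and for LOC4326594 with array weights, where its log2 change of 0.98 was under the threshold of 1. List calls were lost for cell cycle genes (adjusted p = 0.192), core histones (0.546) and DNA replication factors (0.814) without Mei1 replicate 1, for the last also without An1 replicate 3 (0.0723) and with quantile normalization (0.0608), for other floral organs without An1 replicate 2 (0.179) or Mei1 replicate 2 (0.146) and with a pseudocount of 4 (0.0682), and for meiosis without Mei1 replicate 2 (0.0556) or 3 (0.0583) and under spike-in scaling, where its median was -0.02.

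From Mei1 to M1, as anthers entered meiosis at leptotene, most of the change was a rise, and 7 of 17 measured jasmonate response genes took part in it. JAZ11 (LOC4331833) went from 0.587 ± 0.146 to 21.6 ± 6.86 (log2 change 3.77, SE 0.45, adjusted p = 1.25e-05), with 3 arrays in Mei1 and 4 in M1. JAZ12 (LOC4348533) went from 1.41 ± 0.217 to 22.8 ± 6.26 (log2 change 3.27, SE 0.34, adjusted p = 2.35e-06). Both encode JAZ repressors of jasmonate signalling. Other large rises were those of pinA (LOC9268662), from 2.37 ± 1.75 to 44.2 ± 9.0 (log2 change 3.85), and OSE727A (LOC9271230), from 2.50 ± 1.89 to 42.0 ± 10.0 (log2 change 3.72). The homeobox gene HOX12 (LOC4331956) rose from 1.47 ± 1.2 to 22.7 ± 4.59 (log2 change 3.37), and the NAC-family gene NAC4 (LOC4327485) from 0.988 ± 0.398 to 17.3 ± 5.74 (log2 change 3.16). Of 17 JAZ genes measured, 7 rose (8 when adjusted over the list alone) and 10 did not pass. JAZ9 (LOC4331832) rose from 4.42 ± 1.37 to 38.5 ± 5.78. JAZ13 (LOC4348531), chosen after its values were seen, had the largest adjusted p of the 7 (log2 change 2.13, adjusted p = 0.0227). The JAZ list shifted higher (median 0.60, adjusted p = 4.16e-07, and adjusted p = 0.215 with an estimated correlation). The largest falls were those of MEL1 (LOC4334449, 40.2 ± 2.57 to 16 ± 5.77, log2 change -1.34) and of FON1 (LOC4342080), a receptor kinase that limits the floral meristem (7.44 ± 0.458 to 2.68 ± 0.505, log2 change -1.20). The bZIP gene TGAL4 (LOC4349800) fell from 11.9 ± 0.509 to 5.21 ± 1.34 (log2 change -1.08). MSP1 (LOC4324355), a receptor kinase that limits the number of sporogenous cells, fell from 23.2 ± 1.45 to 10.8 ± 0.957 (log2 change -1.03). 1 of 20 calcium-dependent protein kinases rose, CPK13 (LOC4336783, 9.31 ± 0.569 to 29.9 ± 5.48, log2 change 1.57). The list shifted higher (median 0.11, adjusted p = 0.041, and adjusted p = 0.665 with an estimated correlation). The cell cycle genes (median -0.61, adjusted p = 0.00023, and adjusted p = 0.348 with an estimated correlation), DNA replication factors (median -0.44, adjusted p = 2.64e-05, and adjusted p = 0.534 with an estimated correlation) and kinesins (median -0.27, adjusted p = 3.67e-05, and adjusted p = 0.334 with an estimated correlation) shifted lower. The proteasome subunits were lower too (median -0.30, adjusted p = 0.00363, and adjusted p = 0.665 with an estimated correlation). By limma, 0 members of these 4 lists were called, and 11, 17, 19 and 9 of them had an unadjusted p under 0.05. In all, 545 probe sets of 366 genes were called, 520 higher and 25 lower. MSP1 changed by -0.99 without Mei1 replicate 2, by -0.97 without M1 replicate 4 by -0.90 under spike-in scaling and by just under 1 log2 unit (-1.0) with the replicate block and with array weights, TGAL4 by -0.97 without M1 replicate 4 and -0.96 under that scaling, and MSP1, TGAL4 and FON1 by -0.87, -0.80 and -0.78 with a pseudocount of 4, each under the threshold of 1. The proteasome call was lost without Mei1 replicate 2 (adjusted p = 0.0972) and under spike-in scaling (0.0861), and that of the calcium-dependent protein kinases with the replicate block (0.0521), array weights (0.0782) or spike-in scaling (0.0969), without the probe sets that can bind related transcripts (0.191), without P3 replicate 1 and P2 replicate 1 together (0.0602) and without Mei1 replicate 1 (0.0532), Mei1 replicate 2 (0.0725), P2 replicate 1 (0.0504) or P3 replicate 3 (0.05), and JAZ13 lost its call with the replicate block (0.0577), under spike-in scaling (0.0595) and without Mei1 replicate 1 (0.0769), Mei1 replicate 2 (0.0738), Mei1 replicate 3 (0.0651) or M1 replicate 2 (0.0657).

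From M1 to M2, leptotene was compared with zygotene and pachytene, and some genes of the tapetum, the nutritive layer around the meiocytes, rose while others fell. C4 (LOC9270168), a tapetal lipid transfer protein gene, went from 9.29 ± 12.9 to 116 ± 18.5 (log2 change 4.51, SE 0.60), with 4 arrays in M1 and 3 in M2. CYP703A3 (LOC4344594), a fatty acid hydroxylase of pollen wall formation, went from 3.96 ± 1.77 to 43.2 ± 20.6 (log2 change 3.11, SE 0.50). They were 2 of the 4 measured genes of the tapetal lipid list, and C6 and RTS did not pass. That list shifted higher (median 1.98, adjusted p = 0.0087, and adjusted p = 0.215 with an estimated correlation). PTC1 (LOC4347213), a PHD-finger regulator of tapetal cell death, rose from 0.245 ± 0.0469 to 6.20 ± 3.58, and the glutathione transferase gene GST1 (LOC4334347) from 0.434 ± 0.0255 to 7.47 ± 2.18 (log2 changes 2.40 and 2.53). BURP13 (LOC4345929) rose from 1.79 ± 1.12 to 13.2 ± 7.13 and Chia1d (LOC4338720) from 1.69 ± 1.31 to 10.0 ± 7.46 (log2 changes 2.28 and 1.95). C4 ran from 0.241 to 27.9 over the 4 M1 arrays. Of the 8 anther wall and tapetum regulators 2 rose, PTC1 and TDR (LOC4328113, 9.93 ± 4.19 to 21 ± 3.59), and 3 fell. These were MSP1 (10.8 ± 0.957 to 4.56 ± 0.998), TDL1A (LOC4352199, 2.74 ± 0.744 to 0.763 ± 0.138) and, with overlapping replicates, EAT1 (9.29 ± 3.04 to 2.96 ± 2.16). TDR and the 3 that fell were chosen after their values were seen, and the list test did not pass (adjusted p = 0.623). The largest fall was that of MEL1, from 16 ± 5.77 to 1.37 ± 0.625 (log2 change -2.81, SE 0.20), the 1 meiosis gene of 11 to pass. By limma, 10 of the 11 had an unadjusted p under 0.05. The meiosis list shifted lower (median -0.42, adjusted p = 1.15e-10, and adjusted p = 0.00498 with an estimated correlation). This was the 1 list call of the series that held with an estimated correlation. 3 of 6 core histones fell, H2B.7 (LOC4324500) from 24.9 ± 4.39 to 8.74 ± 0.574, H2B.10 (LOC4324495) from 11.5 ± 2.87 to 3.87 ± 0.672 and H2B.6 (LOC4324502) from 36.1 ± 7.73 to 16.5 ± 1.78. The histone list shifted lower (median -0.99, adjusted p = 1.14e-06, and adjusted p = 0.215 with an estimated correlation). 4 of 26 DNA replication factors fell, RPA70b (LOC4332052, 4.04 ± 0.799 to 0.984 ± 0.143), MCM3 (LOC4339099, 4.83 ± 0.527 to 1.70 ± 0.672), PCNA (LOC4331062, 5.79 ± 1.21 to 2.24 ± 1.25) and RPA32 (3.46 ± 0.232 to 1.12 ± 0.499). RPA32 was chosen after its values were seen. The replication factor list shifted lower (median -0.42, adjusted p = 1.61e-07, and adjusted p = 0.346 with an estimated correlation). MCM3 and PCNA were also the 2 of 12 cell cycle genes that fell (median -0.69, adjusted p = 1.14e-06, and adjusted p = 0.334 with an estimated correlation). CAD6 (LOC4335223) fell from 10.5 ± 3.29 to 1.54 ± 0.346 (log2 change -2.13). The zinc finger gene C3H43 (LOC4341164) fell from 2.84 ± 1.3 to 0.334 ± 0.121 and the MAP kinase gene BIMK2 (LOC4328223) from 2.96 ± 1.06 to 0.507 ± 0.0633 (log2 changes -1.46 and -1.35). The 34 kinesins shifted lower with 0 called by limma and 17 at an unadjusted p under 0.05 (median -0.23, adjusted p = 4.81e-05, and adjusted p = 0.334 with an estimated correlation). Of 21 potassium transporters 1 rose, HAK1 (LOC4335729, 2.31 ± 0.396 to 7.06 ± 2.63). The list shifted higher (median 0.09, adjusted p = 0.0256, and adjusted p = 0.346 with an estimated correlation). In all, 405 probe sets of 264 genes were called, 277 higher and 128 lower. Of these, 68.4% were higher, against 58.2% with median-centred arrays and 56.5% under spike-in scaling. Calls were lost for Chia1d without M1 replicate 1 (adjusted p = 0.0534) or M2 replicate 2 (0.0904), for PCNA without M1 replicate 3 (0.0596), M2 replicate 1 (0.118) or M2 replicate 3 (0.0935) and with the replicate block (0.0564), for the potassium transporters without the probe sets that can bind related transcripts (0.138) and without M2 replicate 3 (0.128), where HAK1 changed by 0.99, for TDR without M1 replicate 1 (0.0806), M1 replicate 2 (0.0629), M2 replicate 1 (0.069) or M2 replicate 2 (0.0801) and under spike-in scaling (0.0895), and for EAT1 without M2 replicate 1 (0.0674). RPA32 changed by -0.95 and MSP1 by -0.97 without M2 replicate 3, TDL1A by -0.94 without M1 replicate 2, H2B.6 by just under 1 log2 unit (-1.0) without M1 replicate 2, by -0.96 without M1 replicate 4 and by -0.98 without M2 replicate 3, and H2B.10, H2B.6, RPA32, RPA70b, MCM3, PCNA, C3H43, BIMK2, HAK1, TDR, MSP1, TDL1A and EAT1 changed by less than 1 log2 unit with a pseudocount of 4.

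**Figure D3:**
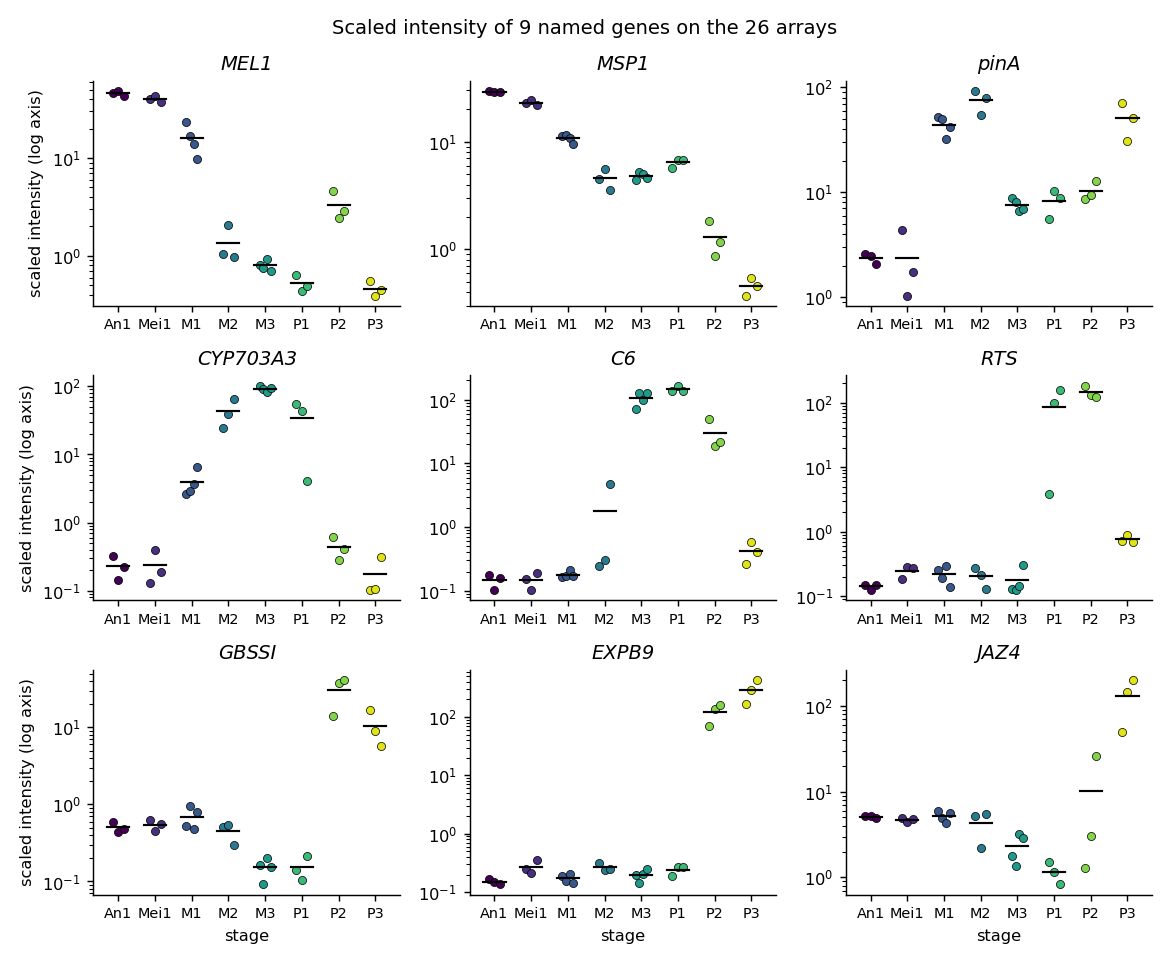
Scaled intensity (y axes, log scale, multiples of the 75th percentile of each array) of 9 named genes on the 26 arrays by stage (x axes); points are arrays and bars are stage means. MEL1 is at 45.8 in An1 and at 3.30 or less in M2 and later stages, C6 reaches 106 in M3, and JAZ4 reaches 132.5 in P3.

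From M2 to M3, zygotene to pachytene was compared with diplotene to tetrads, and C6 and both measured tapetal proteases rose while members of the jasmonate response and heat shock lists fell. C6 (LOC4350790) went from 1.79 ± 2.62 to 106 ± 27.7 (log2 change 5.62, SE 0.36), with 3 arrays in M2 and 4 in M3. AP25 (LOC4331874), an aspartic protease of tapetal cell death, went from 20.3 ± 28.1 to 123 ± 10.7 (log2 change 3.52, SE 0.55). The aquaporin-family gene NIP4-1 (LOC4326119) rose from 8.38 ± 14.1 to 84.6 ± 11.8 and the hexokinase gene HXK6 (LOC4338010) from 4.12 ± 5.31 to 48.0 ± 17 (log2 changes 4.63 and 3.69). The chalcone synthase gene CHS1 (LOC4350636) rose from 4.10 ± 6.35 to 34.5 ± 8.42 and the ketoacyl-CoA synthase gene KCS20 (LOC4348632) from 7.99 ± 2.86 to 57.4 ± 3.28 (log2 changes 3.56 and 2.75). M2 replicate 3 was already higher than the other M2 arrays for C6 (4.81), NIP4-1 (24.6) and AP25 (52.7). Both measured tapetal proteases, CP1 and AP25, rose. That list was too short for a list test. Of 4 tapetal lipid genes 1 rose, C6, and the list test did not pass (adjusted p = 0.0594). Of the 8 anther wall and tapetum regulators EAT1 rose (2.96 ± 2.16 to 16.5 ± 5.99) and TIP2 (LOC4325164) fell (16.7 ± 2.59 to 5.87 ± 1.5), both chosen after their values were seen. The list test of the regulators did not pass (adjusted p = 0.925). The dehydrin genes RAB16B (LOC4350453) and RAB21 (LOC4350454) fell, RAB16B from 28.3 ± 21.7 to 0.248 ± 0.0720 (log2 change -3.99, SE 0.51). RAB21 went from 26.5 ± 22.1 to 0.747 ± 0.313 (log2 change -3.19, SE 0.74). Also falling were the pyruvate decarboxylase gene PDC (LOC4339066, 17.2 ± 20.2 to 0.234 ± 0.00641) and the lipoxygenase gene LOX1.1 (LOC4334049, 11.7 ± 7.67 to 0.423 ± 0.101). HOX12 fell from 33.2 ± 11.8 to 2.47 ± 0.364 and pinA from 75.1 ± 18.7 to 7.59 ± 0.961. On M2 replicate 2 the dehydrins were low (RAB16B 3.53, RAB21 1.47) and PDC was at 40.5. The other M2 arrays had RAB16B at 43.8 and 37.5 and PDC at 5.20 and 5.81. 5 of 17 JAZ genes fell (7 when adjusted over the list alone), led by JAZ12 (28.5 ± 11.8 to 3.90 ± 2.04), JAZ7 (LOC4343899, 30.3 ± 10.2 to 6.22 ± 1.29) and JAZ11 (26.5 ± 12.9 to 6.43 ± 1.51). The other two were JAZ6 (18.7 ± 7.0 to 6.75 ± 1.85) and JAZ8 (9.89 ± 5.97 to 1.82 ± 0.560), chosen after their values were seen. The JAZ list shifted lower (median -0.65, adjusted p = 0.000685, and adjusted p = 0.346 with an estimated correlation). 5 of 44 heat shock proteins and factors fell, among them hsp17.9 (LOC4332357, 27.8 ± 17.6 to 7.57 ± 3.99), HSF24 (LOC4347637, 2.86 ± 1.04 to 0.288 ± 0.0673) and HSF1 (LOC4336701, 6.26 ± 1.43 to 1.76 ± 1.37). The other two, chosen after their values were seen, were HSF25 (4.11 ± 0.410 to 0.975 ± 0.261) and HSP26.2 (LOC4340508, 13.2 ± 6.5 to 5.86 ± 2.01, with overlapping replicates). The heat shock list shifted lower (median -0.27, adjusted p = 0.00396, and adjusted p = 0.539 with an estimated correlation). The 7 stamen identity MADS-box genes (median 0.63, adjusted p = 0.00125, and adjusted p = 0.346 with an estimated correlation) and the 16 proteasome subunits (median 0.39, adjusted p = 1.71e-06, and adjusted p = 0.346 with an estimated correlation) shifted higher. By limma, 0 members of either were called, and 7 and 14 had an unadjusted p under 0.05. In all, 971 probe sets of 656 genes were called, 505 higher and 466 lower, and 12689 had an unadjusted p under 0.05. RAB21 (adjusted p = 0.0797), JAZ11 (0.102), JAZ6 (0.0531) and HSP26.2 (0.0637) lost their calls without M2 replicate 1, HSP26.2 also without M2 replicate 2 (0.158) or M3 replicate 1 (0.0879), hsp17.9 without M2 replicate 2 (0.109) or M3 replicate 3 (0.0513), and the heat shock list without M2 replicate 2, where its median was 0.04 (0.27). HSF24, HSF1, HSF25, HSP26.2 and CP1 changed by less than 1 log2 unit with a pseudocount of 4, and HSP26.2 by -0.92 with array weights, -0.97 with median-centred arrays and just under 1 (-1.0) with the replicate block, and lost its call with a pseudocount of 0.149 (adjusted p = 0.0672).

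**Figure D4:**
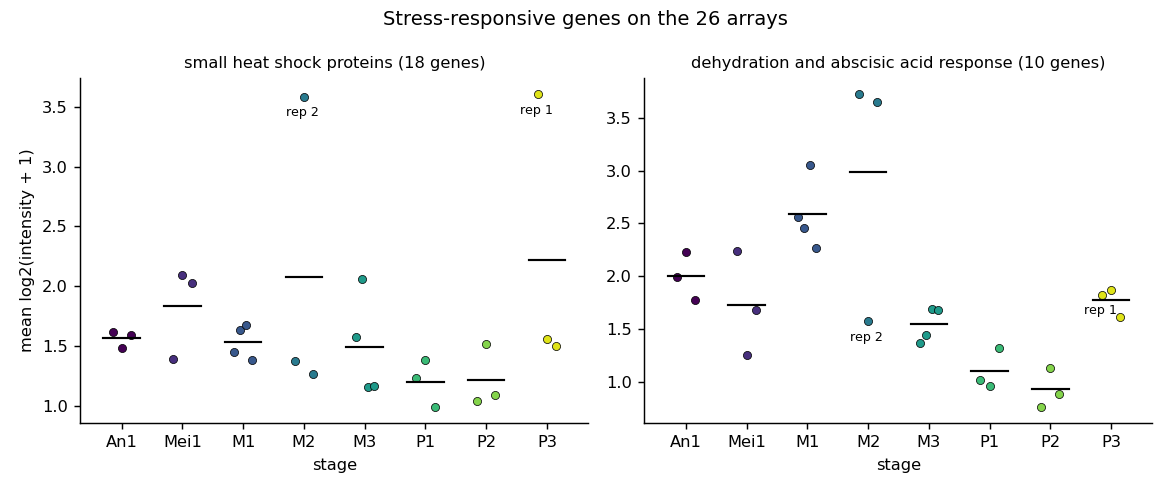
Mean log2(intensity + 1) of the measured members of a small heat shock protein list (left y axis) and a dehydration and abscisic acid response list (right y axis), both written after values were seen, on the 26 arrays by stage (x axes); points are arrays and bars are stage means. The small heat shock protein list is at 3.58 on M2 replicate 2 and 3.60 on P3 replicate 1 against at most 2.10 on the other 24 arrays, and the dehydration list is at 1.57 on M2 replicate 2 against 3.72 and 3.65 on the other M2 arrays.

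From M3 to P1, the end of meiosis was compared with uninucleate microspores, and RTS (LOC4326940), a tapetum gene needed for fertility, rose most among the named genes. RTS went from 0.177 ± 0.0874 to 85.8 ± 76.6 (log2 change 5.17, SE 0.63), with 4 arrays in M3 and 3 in P1. It was at 3.87 on P1 replicate 1 and 97.8 and 156 on the other P1 arrays. The UDP-glucose epimerase gene UGE-3 (LOC4347638) rose from 7.48 ± 4.92 to 45.0 ± 17.5 and the glutamine synthetase gene GLN1-2 (LOC4332108) from 0.604 ± 0.440 to 12.7 ± 13.9 (log2 changes 2.64 and 2.52). P5CS2 (LOC4324853), of proline synthesis, rose from 4.61 ± 2.84 to 24.6 ± 3.95 and CYP714D1 (LOC4339131), of gibberellin deactivation, from 0.968 ± 0.884 to 8.72 ± 2.64 (log2 changes 2.35 and 2.37). The aquaporin gene PIP2;7 (LOC4347729) rose from 0.489 ± 0.0913 to 13.1 ± 15.7 (log2 change 2.39). PTC1 and CYP703A3, which had risen from M1 to M2, fell. PTC1 went from 10.1 ± 3.74 to 1.35 ± 1.04 (log2 change -2.28, SE 0.28). CYP703A3 went from 92.4 ± 8.69 to 34.3 ± 26.7 (log2 change -2.00, SE 0.50), the latter at 4.04 on P1 replicate 3. The auxin response gene IAA1 (LOC4334069) fell from 13.9 ± 2.67 to 3.16 ± 1.67 and the heat shock gene HSP26.2 from 5.86 ± 2.01 to 1.15 ± 0.469 (log2 changes -1.91 and -1.65). EL2 (LOC4331332) fell from 16 ± 11.9 to 3.02 ± 1.34 and the zinc finger gene C3H33 (LOC4337692) from 23.3 ± 16.8 to 5.48 ± 1.73 (log2 changes -1.79 and -1.62). 2 of 12 cell cycle genes fell, the mitotic cyclins CYCB2;2 (LOC4342121, 1.98 ± 0.470 to 0.248 ± 0.147) and CYCB1;1 (LOC4327547, 3.32 ± 0.707 to 0.850 ± 0.213). The cell cycle list shifted lower (median -0.35, adjusted p = 1.15e-05, and adjusted p = 0.334 with an estimated correlation). The 34 kinesins shifted lower with 0 called by limma and 16 at an unadjusted p under 0.05 (median -0.18, adjusted p = 0.0402, and adjusted p = 0.665 with an estimated correlation). In all, 598 probe sets of 406 genes were called, 282 higher and 316 lower. Of these, 47.2% were higher, against 79.9% under spike-in scaling, which moved the median of all probe sets to 0.12 and left CYCB1;1 at -0.99. The count was 387 without P1 replicate 3 and 856 without P1 replicate 1; without P1 replicate 3 the calls of CYP703A3 (adjusted p = 0.0962), PIP2;7 (0.0788), EL2 (0.162) and C3H33 (0.18) were lost, CYP703A3 also without M3 replicate 1 (0.0517), and EL2 and C3H33 also without M3 replicate 3 (0.0965 and 0.137), M3 replicate 4 (0.0869 and 0.137) or P1 replicate 2 (0.0826 and 0.145), with the replicate block (0.0732 and 0.102) and under spike-in scaling (0.0915 and 0.135), CYP703A3 with the block (0.0522), and C3H33 with a pseudocount of 4 (0.0629) and without the trend (0.0502). The kinesin call was lost without M3 replicate 1 (0.0556), M3 replicate 2 (0.0623), P1 replicate 1 (0.118), P2 replicate 1 (0.057), P3 replicate 1 (0.0554) or P3 replicate 3 (0.0505), without P3 replicate 1 and P2 replicate 1 together (0.0752), with the replicate block (0.0608), quantile normalization (0.0518), array weights (0.0726) or a pseudocount of 4 (0.116), and HSP26.2, CYCB2;2 and CYCB1;1 changed by less than 1 log2 unit with a pseudocount of 4.

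From P1 to P2, as microspores became bicellular pollen, some beta-expansin, starch and gibberellin synthesis genes rose and some tapetal genes fell. The beta-expansin gene EXPB9 (LOC4349301) went from 0.243 ± 0.0471 to 124 ± 47.3 (log2 change 6.57, SE 0.24), with 3 arrays in each stage. EXPB10 (LOC4331325) went from 0.134 ± 0.00630 to 65.7 ± 48.2 (log2 change 5.35, SE 0.47). 3 of 10 beta-expansins rose, the third being EXPB2 (LOC4349348, 0.242 ± 0.0883 to 4.58 ± 0.484). 2 others fell, EXPB7 (LOC4331300, 3.93 ± 2.81 to 0.190 ± 0.0537) and EXPB4 (LOC4349350, 17.8 ± 8.09 to 7.79 ± 1.51). EXPB2, EXPB7 and EXPB4 were chosen after their values were seen, and the list test did not pass (adjusted p = 0.26). The beta-glucosidase gene BGLU38 (LOC4352082) rose from 0.146 ± 0.0475 to 87.3 ± 21.5 and ADF1 (LOC4330233), an actin-depolymerizing factor, from 0.255 ± 0.0321 to 43.3 ± 20.2 (log2 changes 6.24 and 5.01). 3 of 6 starch synthesis genes rose, GBSSI (LOC4340018, 0.154 ± 0.0551 to 30.9 ± 14.6, log2 change 4.65), AGPS2 (LOC4345339, 3.35 ± 1.17 to 12.8 ± 1.81, log2 change 1.70) and SSI (LOC9269493, 3.94 ± 1.07 to 10.2 ± 0.15, log2 change 1.2). The other 3 did not pass. The starch list shifted higher (median 0.97, adjusted p = 0.0387, and adjusted p = 0.334 with an estimated correlation). 3 of 6 gibberellin genes rose, all of them early synthesis enzymes, KAO (LOC4339885, 0.580 ± 0.504 to 52.8 ± 13.7, log2 change 5.10), CPS1 (LOC4329013, 0.273 ± 0.309 to 19.7 ± 5.30, log2 change 4.02) and KO2 (LOC4341347, 1.70 ± 0.483 to 9.99 ± 1.27, log2 change 2.03). The gibberellin list shifted higher (median 1.51, adjusted p = 0.00363, and adjusted p = 0.215 with an estimated correlation). Both measured sugar supply genes, the invertase gene INV4 (0.337 ± 0.0216 in P1 and 22.3 ± 14 in P2) and the sucrose transporter gene SUT1 (0.459 ± 0.0409 and 3.06 ± 2.19), rose. That list was too short for a list test. The tapetal genes C4 (128 ± 28.5 to 0.317 ± 0.0861, log2 change -6.59), AP25 (82.6 ± 48.4 to 0.174 ± 0.0263, log2 change -5.90) and CYP703A3 (34.3 ± 26.7 to 0.436 ± 0.173, log2 change -4.03) fell. So did NIP4-1 (84.5 ± 28.6 to 0.306 ± 0.0862), KCS20 (51.2 ± 21.2 to 0.440 ± 0.156) and the lipid transfer protein gene LTP110-A (LOC4349601, 33.0 ± 15.9 to 0.741 ± 0.166). 3 of 4 tapetal lipid genes fell, C4, CYP703A3 and C6 (146 ± 17.3 to 29.9 ± 16.5, chosen after its values were seen), and so did both tapetal proteases, AP25 and CP1. The tapetal lipid list, with a median of -3.20, did not pass the list test (adjusted p = 0.0788). In all, 2617 probe sets of 1859 genes were called, 1544 higher and 1073 lower. Of these, 59.0% were higher, against 34.1% under spike-in scaling, which moved the median of all probe sets to -0.10 and ended the call of SSI (0.84, adjusted p = 0.0832). The starch call was lost without P2 replicate 1 (adjusted p = 0.0502), and the starch (0.359) and gibberellin (0.13) calls without the probe sets that can bind related transcripts; SSI changed by 0.84 with a pseudocount of 4, SUT1 by 0.93 without P2 replicate 2 and CP1 by -0.89 without P1 replicate 1, SUT1, CP1, EXPB7 and EXPB4 by less than 1 log2 unit with a pseudocount of 4, and EXPB4 lost its call with array weights (-0.89) and without P1 replicate 3 (adjusted p = 0.0796) or P2 replicate 3 (0.0545).

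**Figure D5:**
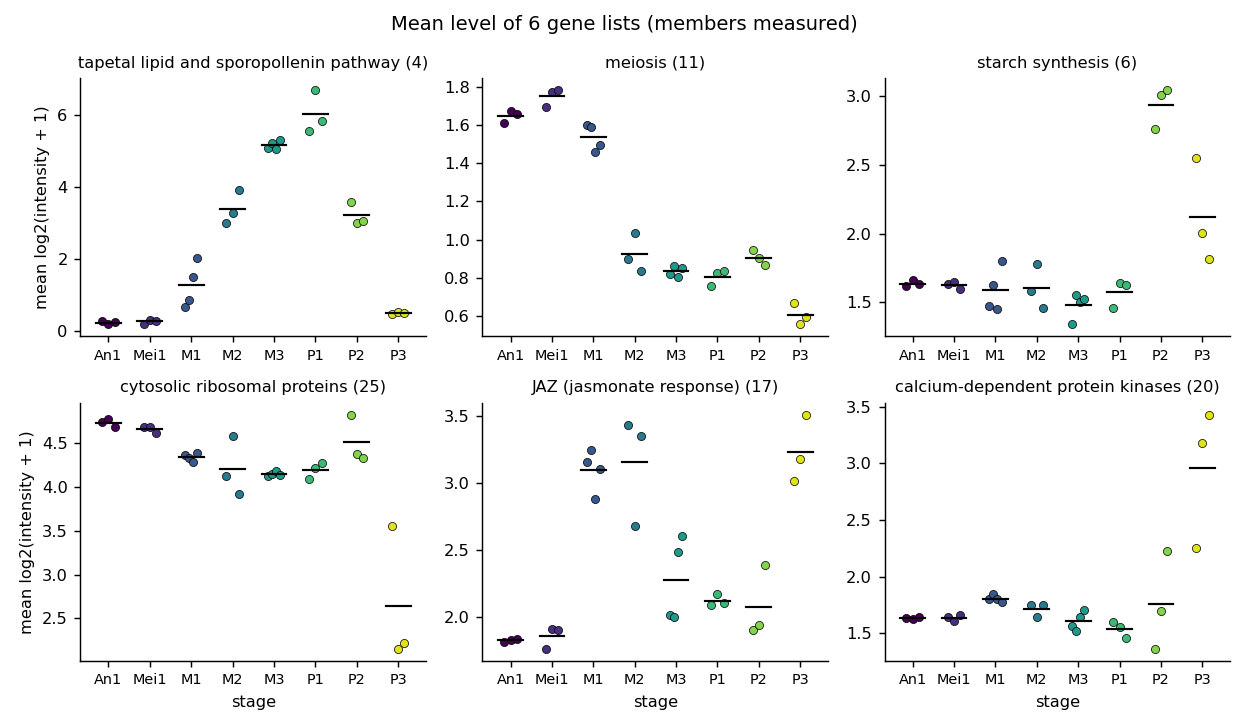
Mean log2(intensity + 1) of the measured members of 6 gene lists (y axes) by stage (x axes); points are arrays and bars are stage means. The tapetal lipid list, with 4 of 17 genes measured, peaks in P1 at 6.03. Among its members, C6 and RTS are higher in P1 than in M3 and CYP703A3 is lower. The JAZ list is at 3.09 in M1, 3.15 in M2 and 3.23 in P3, and the ribosomal protein list drops from 4.51 in P2 to 2.64 in P3, where replicate 1 is the highest of the 3 arrays.

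From P2 to P3, as pollen matured, more transcripts changed than at any other step in the fit of all 26 arrays, and ribosomal protein genes fell nearly as a group. 22 of 25 cytosolic ribosomal protein genes fell, led by RPS26 (LOC4327570, 33.4 ± 10.3 to 5.26 ± 2.78, log2 change -2.50), RPS15 (LOC4342580, 30.4 ± 8.0 to 6.22 ± 6.59, log2 change -2.46) and RPS3A (LOC4331966, 42.2 ± 9.75 to 8.91 ± 8.40, log2 change -2.42), with 3 arrays in each stage. The ribosomal list shifted lower (median -1.92, adjusted p = 3.71e-11, and adjusted p = 0.354 with an estimated correlation), against a median of 0.12 for all probe sets tested. 7 of 17 JAZ genes rose and 1 fell, JAZ13 (19.1 ± 10.5 to 2.34 ± 1.82, chosen after its values were seen). The rises were led by JAZ4 (LOC4347000, 10.2 ± 14 to 132.5 ± 76.1, log2 change 4.19), JAZ11 (2.35 ± 3.51 to 40.1 ± 17.3, log2 change 4.05) and JAZ10 (LOC4331834, 1.40 ± 0.654 to 18.7 ± 3.73, log2 change 3.06). The JAZ list shifted higher (median 0.75, adjusted p = 0.0234, and adjusted p = 0.534 with an estimated correlation). 8 of 20 calcium-dependent protein kinases rose, led by CPK21 (LOC4346187, 5.94 ± 9.63 to 101 ± 87.3), CPK2 (LOC4327560, 7.88 ± 10.5 to 110.1 ± 91.4) and CPK22 (LOC4347564, 13.3 ± 17.3 to 134 ± 111), whose replicates overlapped between the stages. The calcium-dependent protein kinase list shifted higher (median 0.82, adjusted p = 0.0037, and adjusted p = 0.431 with an estimated correlation). 3 of 10 beta-expansins rose, EXPB2 (4.58 ± 0.484 to 31.4 ± 2.03), EXPB8 (LOC4331298, 0.424 ± 0.322 to 5.12 ± 1.92) and EXPB9 (124 ± 47.3 to 293 ± 132). The beta-expansin list shifted higher (median 0.75, adjusted p = 0.0274, and adjusted p = 0.259 with an estimated correlation). The alpha-expansin gene EXPA32 (LOC4346331) rose from 11.6 ± 12.6 to 129.5 ± 97.5, the malic enzyme gene NADP-ME2 (LOC4324717) from 6.27 ± 4.66 to 63.8 ± 14.4 and the silicon channel gene Lsi1 (LOC4330713) from 0.716 ± 0.484 to 14.5 ± 2.20 (log2 changes 3.69, 3.36 and 3.20). RTS fell from 144 ± 33.5 to 0.766 ± 0.109 (log2 change -6.34, SE 0.68) and C6 from 29.9 ± 16.5 to 0.420 ± 0.166 (log2 change -4.33, SE 0.39). So did Chia1d (33.5 ± 9.88 to 1.18 ± 1.41), the light-harvesting gene CAB2R (LOC4324599, 27.7 ± 9.88 to 0.798 ± 0.527), INV4 (LOC4335789, 22.3 ± 14 to 0.531 ± 0.0831) and PIP2;7 (27.2 ± 9.99 to 1.24 ± 0.824). 1 of 7 stamen identity MADS-box genes rose, MADS3 (LOC9271572, 3.44 ± 0.705 to 8.59 ± 3.16). That list shifted higher (median 0.90, adjusted p = 0.0335, and adjusted p = 0.611 with an estimated correlation). Of 6 genes of other floral organs 1 rose, MADS1 (LOC4332059), a regulator of lemma and palea (0.530 ± 0.247 to 3.71 ± 1.54). That list shifted higher too (median 0.53, adjusted p = 0.0387, and adjusted p = 0.346 with an estimated correlation). 1 of 16 proteasome subunits fell, PAD1 (LOC4347710, 14.8 ± 0.362 to 4.28 ± 0.422). The proteasome list shifted lower (median -0.44, adjusted p = 0.0279, and adjusted p = 0.749 with an estimated correlation). P3 replicate 1 differed from the other P3 arrays for some of these genes. JAZ4 was at 50.4 on it against 146 and 201 on the other P3 arrays, CPK21 at 8.52 against 113 and 182 (5.94 ± 9.63 in P2). The ribosomal list mean was the highest of the 3. In all, 3965 probe sets of 2865 genes were called, 2018 higher and 1947 lower (50.9% higher, against 25.2% under spike-in scaling and 34.0% with only these stages' arrays, where 2340 were called, fewer than the 2388 from P1 to P2), and 5101 were called without P3 replicate 1 and 4603 without P3 replicate 1 and P2 replicate 1 together. Calls were lost without P3 replicate 1 for JAZ (adjusted p = 0.0507), beta-expansins (0.0775), other floral organs (0.0885) and proteasome subunits (0.0731); without P2 replicate 1 for stamen MADS-box genes (0.0504), other floral organs (0.0543) and proteasome subunits (0.0717); without P3 replicate 2 for proteasome subunits (0.0533); without P3 replicate 1 and P2 replicate 1 together for JAZ (0.0602), beta-expansins (0.0752), other floral organs (0.138) and proteasome subunits (0.157); with array weights for JAZ (0.0535) and other floral organs (0.0866); for JAZ without the probe sets that can bind related transcripts (0.166, median 0.21); and without P3 replicate 3 (0.0505), under quantile normalization (0.143) or under spike-in scaling (0.137) for stamen MADS-box genes. MADS3 and EXPB9 changed by 0.99 and 0.86 without P2 replicate 1, 0.82 and 0.88 without P3 replicate 3, 0.84 and 0.50 under quantile normalization and 0.56 and 0.63 under spike-in scaling, MADS3 by 0.97 with median-centred arrays, and MADS3 and MADS1 by 0.73 and 0.75 with a pseudocount of 4.

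Stage-enriched transcripts, higher in 1 stage than in each of the other 7, were sought next, and most belonged to anthers of the pollen stages. In P3 anthers, JAZ4 led with 132.5 ± 76.1 against 10.2 ± 14 in P2 (margin 4.19 log2 units), followed by EXPA32 (margin 3.69), NADP-ME2 (margin 3.36) and Lsi1 (14.5 ± 2.20 against 0.776 ± 0.0538 in M2, margin 3.12). In P2 the leading genes were INV4, a cell wall invertase (22.3 ± 14 against 0.531 ± 0.0831 in P3, margin 3.77), BGLU38 (margin 2.72), ASA1 (LOC4334640; 31.7 ± 15.7 against 4.10 ± 0.398 in An1, margin 2.58) and the potassium transporter gene HAK26 (LOC4345999; 20.4 ± 3.8 against 3.41 ± 2.89 in P1, margin 2.50). In P1 they were UGE-3 (margin 2.64), BURP3 (LOC4324159; 43.8 ± 30.6 against 8.67 ± 2.50 in M3, margin 2.0), GST-I (LOC4325710; 6.23 ± 1.29 against 1.81 ± 0.752 in M3, margin 1.39) and GT7 (LOC4330569; 4.95 ± 1.87 against 1.27 ± 0.373 in M3, margin 1.35). ACLA-2 (LOC9272295), an ATP-citrate lyase subunit gene, was the 1 named gene of M3 (106 ± 22.3 against 47.3 ± 18.9 in M2, margin 1.21). Of 3 named genes of M2 only CAD8C (LOC9269515) had no replicates overlapping with other stages (4.48 ± 0.838 against 1.77 ± 0.997 in M3, margin 1.04). By limma, 1413 probe sets of 939 genes were enriched in P3, 421 of 302 genes in P2, 109 of 70 genes in P1, 48 of 27 genes in M3, 21 of 11 genes in M2, and 6 of 2 genes in M1. By limma, 0 were enriched in Mei1 and in An1, where 31 and 422 probe sets were higher than in each other stage at an unadjusted p under 0.05. The 2 genes of M1, chosen after their values were seen, were LOC4331336 (13.3 ± 3.92 against 4.82 ± 1.69 in M2, margin 1.29) and LOC4341367 (42.2 ± 5.68 against 15.7 ± 4.45 in Mei1, margin 1.40). Of the 11560 probe sets that changed over the stages, 2230 had their highest mean in An1 and 574 in Mei1, whose profiles correlated at 0.995. The count for M3 was 16 without M3 replicate 1, 23 without M2 replicate 1, 28 without P1 replicate 3, 76 without M2 replicate 3 and 104 without P1 replicate 1, that for M2 was 13 without M1 replicate 1 and 53 without M2 replicate 2, and that for M1 was 10 without M1 replicate 4. Under spike-in scaling the counts were 22 for M3, 248 for P1 and 713 for P3.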

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

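The tests of the 3 patterns in this part were chosen after the results were seen. P3 replicate 1 stood apart from the other P3 arrays. Scaling of the array, which leaves ranks alone, is argued against by its mean rank correlation with them, 0.826, below the lowest in any other stage, 0.918. Labels exchanged with a P2 array are argued against by its highest correlation with a P2 array, 0.890, below the lowest among the P2 arrays, 0.925. Anthers at a point between P2 and P3 cannot be told apart from another difference of this array: over 5098 probe sets called between P2 and the other P3 arrays it lay 40.5% of the way at the median, against 51.6% or more in 39 such comparisons of other arrays left out, but this restates that it stood apart, and the medians were 24% for the higher and 57.6% for the lower in P3. A mixture of P2 and P3 anthers would put both groups at about the same share of the way on the linear scale, but the medians were 11% for the higher (quartiles 0.0904% and 33.1%) and 72.9% for the lower (52.1% and 91.5%).

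Small heat shock protein transcripts were high on M2 replicate 2 and P3 replicate 1, with list means of 3.58 and 3.60 against at most 2.10 on the other 24 arrays, and 17 of 18 members on the former and all 18 on the latter were higher than on each other array of the stage. Short labelled RNA as a cause of both is argued against, since the 3′ minus 5′ signal of the rice control transcripts was 0.70 on P3 replicate 1, within 0.45 to 1.19 on the other 24 arrays, while M2 replicate 2 was at 1.61, above them, with labelling controls at 2.76 against at most 1.83 on the other 25, so for that array alone it stays open. Anthers of a neighbouring stage are argued against, since the mean of the other 26 heat shock list members, a list set before values were examined, was above every array of the neighbouring stages on both, 2.17 against at most 1.89 on M2 replicate 2 and 1.79 against at most 1.58 on P3 replicate 1 (the smaller excess 0.21). That comparison covers the sampled stages alone, and anthers at a point between them were not tested. The labels give no temperature or time of collection, so no biological explanation was tested.

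Some jasmonate response genes were high in M1, M2 and P3. The camera calls of the list did not hold with an estimated correlation (adjusted p = 0.215 from Mei1 to M1 and 0.534 from P2 to P3). Array scaling is argued against for M1 and P3, since of 17 JAZ genes 6 were called higher from Mei1 to M1 under each of 4 scalings, the one in use included, and 7 from P2 to P3. For M1 and M2, dehydration of the collected anthers cannot be told apart from a difference between the stages, because the dehydration list was 0.86 and 1.26 higher there than in Mei1. In M1, however, the dehydration list was highest on replicate 3 (3.06), where the JAZ list was lowest (2.88). In M2 it was high on replicates 1 and 3 (3.72 and 3.65) but at 1.57 on replicate 2, where the JAZ list was lowest too (2.67). On that array the dehydration list was under its Mei1 mean (1.73), while the JAZ list was above its own Mei1 mean (1.86). For P3 dehydration cannot be told apart either, since that list was 0.84 higher than in P2 and pollen maturation could raise it too. The dehydration list was at 1.77 in P3, against 2 in An1 and 1.73 in Mei1. The JAZ list was at 3.23 in P3, against 1.82 in An1 and 1.86 in Mei1. A difference between the stages stays open, as untested; 2 of 6 jasmonate synthesis probe sets rose from Mei1 to M1 and 2 of 6 from P2 to P3.

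In the 2 stages with 4 arrays, 126 sets of values were compared, and in 10 of them 1 array stood apart by Dixon's ratio of its gap to the range of the 4. Chance alone gives about 5%, or 6.3 sets. Values are log2. JAZ11 was lowest on M1 replicate 3 (3.63, nearest other 4.63, ratio 0.876). CAD6 was lowest on M1 replicate 4 (2.71, nearest other 3.69, ratio 0.934). The anther wall and tapetum regulators list mean was lowest on M1 replicate 1 (2.83, nearest other 3.0, ratio 0.869). The actin cytoskeleton list mean was highest on M1 replicate 3 (1.85, nearest other 1.81, ratio 0.902). AP25 was lowest on M3 replicate 3 (6.76, nearest other 7.01, ratio 0.892). RTS was highest on M3 replicate 4 (0.39, nearest other 0.19, ratio 0.893). The DNA replication and mitotic cell cycle list mean was lowest on M3 replicate 4 (1.39, nearest other 1.55, ratio 0.860). The anther sugar supply list mean was lowest on M3 replicate 2 (0.50, nearest other 0.58, ratio 0.920). The gibberellin synthesis and signalling list mean was highest on M3 replicate 3 (1.48, nearest other 1.38, ratio 0.981). The beta-expansins list mean was lowest on M3 replicate 4 (1.16, nearest other 1.22, ratio 0.837).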

How the results depend on the processing

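Scaling to the spike-in controls, a pseudocount of 0.149 and the joint omission of P3 replicate 1 and P2 replicate 1 were chosen after the results were seen. The 17 counts were those of the change over the stages, the 7 transitions, the 8 stage-enriched sets and the list shifts. All 17 stayed within 1.5 times their values without the filter, with the stricter filter, with quantile normalization, with median-centred arrays, without the trend, without probe sets that can bind related transcripts, with the replicate number as a block and in the joint omission. A pseudocount of 1 was the value in use and was not run again. Values near background carry the least information: a larger pseudocount compresses low intensities by construction, and the counts follow it.

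With a pseudocount of 4, 5070 probe sets changed over the stages. The 7 transitions in order gave 3, 153, 153, 328, 231, 1081 and 1786, and M1 to P3 had 3, 5, 24, 47, 175 and 818 enriched. With 0.149, 20856 changed over the stages, the transitions from Mei1 to M1 onward gave 1154, 1104, 2144, 1286, 5251 and 7263, and M1 to P3 had 13, 52, 83, 179, 680 and 2134 enriched. With 1 probe set per gene, 17338 were tested in place of 47799, which by itself lowers counts. It gave 4 from An1 to Mei1 and 264 from M1 to M2, and 2, 11, 30, 66 and 913 enriched in M1, M2, M3, P1 and P3. From An1 to Mei1 there were 36 with array weights, 35 with only the arrays of these stages and 3 under spike-in scaling. With only the arrays of these stages there were 2340 from P2 to P3, and spike-in scaling gave 22, 248 and 713 enriched in M3, P1 and P3. For these the cause was not tested. The 36 list shifts became 1 with an estimated correlation, which was above the preset 0.01 for 21 of the 24 lists (-0.0994 to 0.707), and 56 with fry, which asks another question (27 were shared).

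Without 1 array at a time, the change over the stages ran from 11089 to 12396. The transitions ran from 0 to 15, 380 to 592, 330 to 483, 656 to 1123, 387 to 856, 2370 to 3029 and 3303 to 5101. Enriched sets ran from 5 to 10 in M1, 13 to 53 in M2, 16 to 104 in M3, 93 to 143 in P1, 386 to 452 in P2 and 1051 to 2006 in P3, and list shifts from 30 to 41. An1 and Mei1 had 0 enriched under every setting. A stage with 2 arrays left is assumed to vary like the others. The DNA replication factors list turned from lower to higher in camera's direction from An1 to Mei1 without Mei1 replicate 1, where its median was -0.013 (adjusted p = 0.814, from 8.55e-06 to 0.814 over its alternatives). Its median ran from -0.24 to -0.013 without single arrays, and the cause was not tested.

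The 101 changes of named genes kept their direction under every setting in which they were compared. Without probe sets that can bind related transcripts, only 88 of them were compared. JAZ4, JAZ10, GBSSI, KO2 and PTC1 were among the genes that could not be compared there. With a pseudocount of 4, 20 no longer passed, 8 under spike-in scaling, 5 with the block (MSP1, CYP703A3, EL2, C3H33 and PCNA), 2 with quantile normalization, and 1 each with centring, without the trend and with array weights, and 15 failed without some array. Of 190 changes of other list members and genes, 101 no longer passed with a pseudocount of 4, 38 under spike-in scaling and 12 with quantile normalization. Of the 36 list shifts, 16 failed without some array. Other losses were those of 6 in the joint omission, 5 without probe sets that can bind related transcripts, 4 with array weights, 4 under spike-in scaling, 3 with quantile normalization, 2 with a pseudocount of 4 and 2 with the block (calcium-dependent protein kinases from Mei1 to M1 and kinesins from M3 to P1). Replicate numbers were not taken to pair the arrays, since the labels state no such design. The mean correlation of residuals was 0.00431 over 85 pairs with the same number (16 above 0.1) and -0.00117 over 210 others (40 above 0.1). Over the 21 same-numbered pairs of consecutive stages it was 0.0673 (-0.3 to 0.538, 9 of the 21 above 0.1), so pairing of some arrays is not excluded.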

Other observations

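The tests of splits in this part were chosen after the results were seen, and so were the genes that the report has not named.
Some genes of the actin cytoskeleton changed as pollen became bicellular. Of 27 genes of the actin cytoskeleton, 6 rose from P1 to P2, among them the actin-depolymerizing factor genes ADF6 (LOC4336623, 0.566 ± 0.411 to 20.3 ± 4.59), ADF9 (LOC4343240, 0.0993 ± 0.0143 to 24.1 ± 17.6) and ADF10 (LOC4349142, 1.76 ± 0.483 to 8.40 ± 0.743), the villin gene VLN4 (LOC4336902, 0.283 ± 0.0394 to 20.4 ± 12.1) and the actin gene ACT1 (LOC4333919, 45.1 ± 5.62 to 141 ± 35.3), with 3 arrays in each stage. The actin gene ACT3 (LOC4334702, 11.7 ± 1.78 to 4.92 ± 0.383) was the 1 that fell, and 7 rose when adjusted over the list alone. From P2 to P3 ADF10 fell (8.40 ± 0.743 to 1.25 ± 0.488), and 4 rose: ADF7 (LOC4337605, 6.93 ± 1.32 to 34.0 ± 21.3), and, with overlapping replicates, ADF9 (24.1 ± 17.6 to 92.1 ± 55.2), ADF1 (43.3 ± 20.2 to 132 ± 80.7) and VLN2 (LOC4332869, 31.3 ± 12.8 to 101 ± 65.3). The list test did not pass at either step (adjusted p = 0.993 and 0.0951), and 15 of the 27 changed over the 8 stages.
From M3 to P1, 2 of 27 cellulose synthase and related genes rose, CESA4 (LOC4324625, 1.96 ± 0.935 to 7.09 ± 3.68) and CESA7 (LOC4348853, 0.797 ± 0.321 to 4.58 ± 2.98), both of secondary cell walls. From P1 to P2, 5 fell, CESA5 (LOC4334710, 4.18 ± 0.963 to 1.16 ± 0.194), CESA6 (LOC4342850, 6.17 ± 2.16 to 1.46 ± 0.360), CSLA9 (LOC4341571, 5.0 ± 0.762 to 0.916 ± 0.617), CESA1 (LOC4337958, 16.4 ± 3.05 to 7.59 ± 0.856) and, with overlapping replicates, CESA4 (7.09 ± 3.68 to 2.67 ± 2.58), while CSLH1 (LOC4348359, 3.03 ± 0.565 to 8.38 ± 0.255) rose. From P2 to P3, 2 rose with overlapping replicates, CSLC9 (LOC4334258, 4.10 ± 3.88 to 40.5 ± 32.9) and CSLD5 (LOC4340943, 1.83 ± 2.14 to 23.9 ± 18.4), and CESA4 fell (2.67 ± 2.58 to 0.264 ± 0.0747). The list test passed at none of the 7 transitions (adjusted p from 0.179 upward), and 18 of the 27 changed over the stages.
Of 21 potassium transporters, 15 changed over the stages. From P1 to P2, 5 rose, HAK26 (3.41 ± 2.89 to 20.4 ± 3.8), HAK2 (LOC4326793, 3.54 ± 0.174 to 14.3 ± 2.62), HAK10 (LOC4341573, 3.36 ± 0.344 to 11.5 ± 3.92), HAK15 (LOC4336950, 4.10 ± 0.0945 to 9.61 ± 1.86) and HAK25 (LOC4330614, 1.90 ± 0.205 to 5.15 ± 0.410), and HAK12 (LOC9270408, 2.48 ± 0.262 to 0.644 ± 0.166) fell. From P2 to P3, 4 others rose, HAK1 (6.61 ± 2.40 to 32.2 ± 11.8), HAK18 (LOC4347862, 3.17 ± 1.68 to 27.1 ± 14.7), HAK20 (LOC4329489, 0.429 ± 0.507 to 9.0 ± 6.88) and HAK9 (LOC4344288, 0.709 ± 0.226 to 2.98 ± 0.736), while HAK26 (20.4 ± 3.8 to 1.52 ± 0.181) and HAK2 (14.3 ± 2.62 to 5.18 ± 1.59) fell.
Without single arrays, ADF1 changed by 0.97 from P2 to P3 (without P2 replicate 1) and VLN2 lost its call without P3 replicate 2 (adjusted p = 0.0504) or 3 (0.0588). CESA4 lost its calls without P1 replicate 3 (0.0766 from M3 to P1 and 0.0569 from P1 to P2), P2 replicate 2 (0.057), P2 replicate 3 (0.0561) or, from P2 to P3, P2 replicate 1 (-0.79). CESA1 changed by -0.92 to -0.99 without P1 replicate 1 or 2 or P2 replicate 2 or 3, and HAK15 by 0.96 and 0.97 without P2 replicate 2 or 3. Under quantile normalization and spike-in scaling, HAK15 changed by 0.89 and 0.67, ADF1 by 0.75 and 0.86 and VLN2 by 0.70 and 0.82, and under spike-in scaling HAK25 changed by 0.77, HAK9 by 0.79 and CSLH1 by 0.88. CESA4 changed by -0.94 from P2 to P3 with array weights and by -0.74 in the joint omission of P3 replicate 1 and P2 replicate 1. With a pseudocount of 4, ACT3, CESA1, CESA4, CESA5, CESA6, CESA7, CSLA9, CSLH1, HAK9, HAK12, HAK15 and HAK25, and HAK2 from P2 to P3, changed by less than 1 log2 unit.

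Lipid transfer protein genes changed at different stages. Of 5 measured, LTP110-A rose from M2 to M3 (11.7 ± 3.30 to 38.1 ± 7.24). From P1 to P2 LTP110-A and LTPL1 (LOC4332993, 10.0 ± 3.88 to 3.88 ± 1.40) fell and LTP (LOC4351318, 1.96 ± 0.727 to 7.80 ± 2.08) rose. From P2 to P3, 3 rose, LTPL1 (3.88 ± 1.40 to 20.7 ± 1.5), LTP (7.80 ± 2.08 to 20.1 ± 7.27) and LTP2-B (LOC4351317, 0.410 ± 0.122 to 3.32 ± 2.79). Over the stages 4 of the 5 changed.
Of 11 alpha-expansins 10 changed over the stages. EXPA32 (0.136 ± 0.0241 to 11.6 ± 12.6) and EXPA26 (LOC4352454, 0.247 ± 0.0650 to 8.96 ± 7.66) rose from P1 to P2, and EXPA7 (LOC4334606, 53.6 ± 16.5 to 10.2 ± 5.32) fell, as did, with overlapping replicates, EXPA2 (LOC4327568, 5.21 ± 5.43 to 1.19 ± 1.05) and EXPA5 (LOC4330706, 6.77 ± 3.17 to 2.23 ± 1.27). From P2 to P3 EXPA1 (LOC4335222, 0.253 ± 0.153 to 2.80 ± 0.646) rose with EXPA32, and EXPA7 fell (10.2 ± 5.32 to 1.41 ± 0.467). Of 10 beta-expansins 9 changed over the stages.
Of 6 photosynthesis genes 5 changed over the stages. CAB2R and PSAH (LOC4339593, 2.28 ± 0.537 to 0.405 ± 0.0666), a photosystem subunit gene, fell from P2 to P3, and 3 fell when adjusted over the list alone, with LHCP (LOC4333359, 3.29 ± 0.646 to 0.672 ± 0.193) added. CAB2R was called higher from M2 to M3 with overlapping replicates (18.6 ± 18 to 58.2 ± 27.7), a call lost without M2 replicate 1 (adjusted p = 0.256), M2 replicate 3 (0.108) or M3 replicate 1 (0.0595), 3 (0.0834) or 4 (0.09) and with the replicate block (0.0672).
Of 42 auxin response genes 30 changed over the stages. From P1 to P2, 7 rose, among them IAA10 (LOC4331149, 3.79 ± 1.99 to 14.9 ± 0.681) and IAA17 (LOC4338160, 34.1 ± 1.91 to 74.7 ± 5.16), and 6 fell, among them the auxin response factor genes ARF15 (LOC9268260, 5.64 ± 1.61 to 1.57 ± 0.20) and ARF7 (LOC4329672, 10.0 ± 1.2 to 3.23 ± 1.33). Of the 42, 5 fell from P2 to P3, the most strongly IAA17 (74.7 ± 5.16 to 13.7 ± 7.24) and IAA21 (LOC4340939, 15.4 ± 8.62 to 1.47 ± 0.282), and 4 rose, 3 of which lost their calls under spike-in scaling and all 4 with a pseudocount of 4. The alpha-expansin, lipid transfer protein, photosynthesis and auxin lists passed the list test at none of the 7 transitions. Of 44 heat shock genes, 3 rose from P2 to P3, HSP18.8 (LOC4343386, 2.55 ± 0.669 to 14.6 ± 2.18), HSP17.4 (LOC4332360, 2.36 ± 1.93 to 11.4 ± 4.58) and CLPB1 (LOC4339343, 0.465 ± 0.148 to 3.17 ± 1.89), and 3 fell, HSP81-3 (LOC4347405, 146 ± 15.1 to 64.5 ± 32.8), HSP81-2 (LOC4347402, 37.6 ± 7.10 to 15.1 ± 12.6) and CLPB-C (LOC4333161, 6.37 ± 1.18 to 2.58 ± 1.26), and the list test did not pass (adjusted p = 0.153). HSP17.4 lost its call without P2 replicate 1 (0.156) or 3 (0.0739) or P3 replicate 1 (0.0883), 2 (0.0547) or 3 (0.0832), and CLPB1 without P2 replicate 1 (0.0588) or 3 (0.0566) or P3 replicate 1 (0.0817). Both lost them with median-centred arrays (0.076 and 0.0548), under spike-in scaling (0.152 and 0.105) and in the joint omission of P3 replicate 1 and P2 replicate 1 (0.248 and 0.133), and HSP17.4 also with quantile normalization (0.0911), without the trend (0.0502) and with array weights (0.124). CLPB-C changed by -0.98 and -0.91 without P3 replicate 2 or 3 and by less than 1 with quantile normalization, and CLPB1 and CLPB-C by less than 1 log2 unit with a pseudocount of 4. None of the 10 late pollen genes could be matched to a probe set.
LTPL1 changed by -0.96, -0.99 and -0.97 from P1 to P2 without P1 replicate 1, P1 replicate 2 or P2 replicate 1, and LTP2-B by 0.93 without P3 replicate 1. EXPA26 lost its call without P2 replicate 3 (adjusted p = 0.0589), EXPA2 without P1 replicate 2 (0.0871), P1 replicate 3 (0.332), P2 replicate 2 (0.17) or P2 replicate 3 (0.133), and EXPA5 without P1 replicate 1 (0.111), P1 replicate 2 (0.173), P2 replicate 2 (0.144) or P2 replicate 3 (0.116). Under spike-in scaling IAA17 changed by 0.67 from P1 to P2 (adjusted p = 0.211) and LTP by 0.67 from P2 to P3, and under quantile normalization they changed by 0.74 and 0.87. In the joint omission LTPL1 changed by -0.97 and LTP2-B by 0.85, the latter by 0.66 with array weights. With a pseudocount of 4, LTPL1, LTP, LTP2-B, EXPA1, EXPA2, EXPA5, PSAH, ARF7 and ARF15 changed by less than 1 log2 unit.

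Over the stages, the counts of changed members in the other lists were 4 of 4 for the tapetal lipid list, 2 of 2 for tapetal proteases, 5 of 6 for starch synthesis, 2 of 2 for sugar supply, 6 of 6 for gibberellin, 5 of 7 for stamen MADS-box genes and 2 of 6 for other floral organs. They were 6 of 6 for core histones, 14 of 44 for heat shock proteins and factors, 5 of 16 for proteasome subunits, 16 of 20 for calcium-dependent protein kinases, 24 of 34 for kinesins, 18 of 26 for DNA replication factors and 10 of 17 for JAZ genes. MCM and PCNA genes stand in both the cell cycle and the replication factor list, and PSS1 in both the meiosis and the kinesin list.
P3 replicates 2 and 3 had means of 2.40 and 2.72 over their probe sets, against 1.41 to 1.80 on the other arrays. Their 100 most intense probe sets held 14.4% and 16.8% of the signal, and their hybridization controls were at 4.75 and 5.36 on the log2 scale, against 3.57 to 4.5. No pair among the 325 pairs of arrays was a duplicate, and the highest correlation was 0.995.

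Other splits of the same arrays were tested for each count. From Mei1 to M1, 545 probe sets were called and at most 151 in another of the 35 splits, from M1 to M2 405 and 252, from M2 to M3 971 and 404, and from M3 to P1 598 and 319. In each, 1 of 35 splits, the real one, gave as many, the smallest share that 35 splits can give. The shares were not adjusted over the transitions, so chance is unlikely but not excluded. The 10 splits of An1 and Mei1 (10 and 0 at most in another), of P1 and P2 (2617 and 31) and of P2 and P3 (3965 and 2175) are too few for a share under 0.05. The 2175 came from the split that exchanged P2 replicate 3 and P3 replicate 1. For the change over the 8 stages, 11560 probe sets were called and at most 2188 in the other splits, 1 of 100 giving as many, so chance alone is unlikely.
For the stage-enriched counts, labels were exchanged over all 26 arrays, so differences between other stages can widen the spread in these splits. No other split gave as many for M3 (48, at most 1 in another split, 1 of 100 as large), P1 (109, 0, 1 of 100) and P2 (421, 1, 1 of 100). This argues against stage labels without any meaning, but cannot test chance for the count of a single stage. Another split gave more than the real count for M1 (6, 7, 2 of 100), M2 (21, 452, 3 of 100) and P3 (1413, 1615, 2 of 100). Their shares were under 0.05 but not adjusted over the stages, so chance is not excluded for these. Nor can chance be excluded for the 36 list shifts (at most 55 in another split, 29 of 100 as large). By limma, 0 probe sets were enriched in An1 and in Mei1, so 100 of 100 splits gave as many whatever their labels, and nothing was tested (at most 0 and 379 in another). Splits that gave 379 for Mei1 and 452 for M2, many times the real counts, may reflect a structure of the samples, which was not tested.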
